A study of Mus musculus with 6 samples.

How the data were processed

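Messenger RNA levels were measured by RNA sequencing in 6 libraries from 4T1, a mouse mammary carcinoma cell line that is widely used as a model of triple-negative breast cancer. In 3 libraries the cells carried a lentiviral vector (pLVX-IRES-neo) expressing mouse Limch1, here called Limch1_OE, and in 3 libraries they carried the empty vector, here called Vector. Per the labels' protocols, virus was packaged in HEK293T cells, antibiotic selection of stable lines began 48 h after infection, the medium held 10% fetal bovine serum, total RNA was extracted with TRIzol and libraries followed standard Illumina protocols. Groups and replicate numbers were taken from the sample titles, because another label field numbers the overexpressed gene and the cell line consecutively through the series. The labels do not say whether the libraries of a group came from separate infections, lines or cultures, so p-values measure the spread between these libraries, which may be technical. No library of uninfected cells was analysed here.

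The deposited table gives FPKM (fragment counts normalised for transcript length and library size) for each transcript in each of the 6 libraries, printed to 2 decimals. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10, featureCounts 2.0.1 and StringTie 2.2.1 with the mouse build mm10, without saying which of them made the FPKM values. The annotation release, the use of strand, the treatment of reads that match several places and any filter on transcripts are not given in the sources used here. The table lists 77865 transcripts of 26094 genes. It lists no counts, and low values of short single-transcript genes showed no whole-read steps, so the depth is unknown and no count test was run. Because no depth is known, no counting interval is given, and the precision of each value is the SD over 3 libraries. No pair of the 6 columns held identical values.

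The listed transcripts were summed per gene, because the table is by transcript whereas the test had been planned for a table by gene. Symbols and coordinates came from GENCODE release M21, whose assembly is mm10, which matched 26033 of the 26094 gene identifiers. The table did not list every annotated transcript. Of 10374 protein-coding genes with a mean of at least 1 FPKM and an annotated principal transcript, 9839 (94.8%) had every principal transcript listed and 116 had none listed. A sum can then miss part of a gene, as for the reference gene Gapdh, whose listed transcripts summed to between 8.35 and 19.92 FPKM. Levels of genes can thus be understated, and the Gapdh range over the 6 libraries shows that a listed sum can also vary between libraries. Whether such variation is technical was not tested.

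Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 11842 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), Limch1_OE minus Vector, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All fold changes given as log2 are on this log2(FPKM + 1) scale, which understates the change of genes with low values. Ratios of mean FPKM are named as such. Single values were compared by the exact two-sided permutation test of the group means, which cannot go below 0.1 for 3 libraries against 3. Reads shared between near-identical copies may be split between them in ways the sources do not describe, which applies to Ifit3 and Ifit3b, Tgtp1 and Tgtp2, the H2-Q and H2-T genes, the NKG2D ligands Ulbp1 and H60b, ribosomal protein genes with processed pseudogenes, and mitochondrial genes with nuclear copies.

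Before the data were examined, 42 gene lists were written: checkpoint ligands, PD-L1 regulators, MHC class I, MHC class II, type I interferon-stimulated genes, interferon-gamma response, chemokines and cytokines, NF-kB targets, JAK-STAT3, actomyosin, focal adhesion, YAP/TAZ targets, epithelial, mesenchymal, extracellular matrix, TGF-beta response, G1/S and replication, G2/M and mitosis, replication histones, p53 targets, apoptosis, unfolded protein response and ATF4, hypoxia, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, cholesterol synthesis, fatty acid metabolism, NRF2 and antioxidants, MAPK and immediate-early genes, Wnt, Notch, lysosome and autophagy, deubiquitinating enzymes, markers of leukocytes, of fibroblasts, of endothelium and of adipocytes and muscle, LIM-domain relatives of Limch1, reference genes, and RNAs read as signs of RNA quality. The 37 lists with at least 5 tested members were compared with all other tested genes by camera in limma with the preset correlation of 0.01, Benjamini-Hochberg adjusted over these lists. The tests, the main alternatives and the rule for named genes were also written before the data were examined. The rule names Limch1 and Cd274. It adds the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean of at least 5 FPKM, groups that do not overlap and a gene symbol that is not a placeholder. It also adds up to 4 members with the smallest p of each list described, and every called member of the MHC class I and checkpoint lists.

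The gene and list tests were first tested on simulated data. Noise was drawn independently for each gene and library, with the SD that eBayes fitted to the real libraries. With 200 of 11702 genes changed, the test recovered 83.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 97.0% of those changed 4-fold. Of 195 calls, 11 were false. None of 40 lists of unchanged genes was called, and a list of changed genes was. Simulated genes were uncorrelated, whereas the estimated correlation was 0.17 in the type I interferon list and 0.92 in the mitochondrially encoded list. The simulation therefore cannot show how often the preset correlation calls lists of correlated genes falsely. Alternatives tried were other pseudocounts, filters and scalings (a common sum of 1000000 per library, the trimmed mean of M values, and quantile normalization), the eBayes variants, a minimum fold of 1.2, a replicate block, each library left out in turn, and list tests with an estimated correlation or by fry. Alternatives added after seeing the data were the most abundant transcript per gene, only genes with every principal transcript listed, removal of mitochondrial genes, removal of each library's GC trend, and lists without interferon or MHC members.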

Results

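RNA sequencing profiled 4T1 mouse mammary carcinoma cells with stable lentiviral expression of Limch1 (Limch1_OE, n = 3 libraries) and cells with the empty vector (Vector, n = 3 libraries). LIMCH1 is an actin-associated protein with a calponin-homology and a LIM domain that activates non-muscle myosin II. The values were FPKM summed over the listed transcripts of each gene. The sums per library lay between 421767 and 425064 FPKM in Limch1_OE and between 414837 and 416242 FPKM in Vector, and the sequencing depth behind them is unknown. Between 11621 and 11860 genes per library reached 1 FPKM. On the tested genes, the first principal component held 74.9% of the variance and separated the groups. The second held 8.98% and set Limch1_OE replicate 1 apart from the other Limch1_OE libraries.

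The comparison asked how Limch1 expression changes the transcriptome of these cells, with attention to PD-L1, which the series title names. Interferon-stimulated genes were the group that differed most. They were 16.2-fold lower in Limch1_OE for Ly6e, 23.4-fold lower for Usp18 and 30.9-fold lower for Ifit3, as ratios of mean FPKM, and 49 of 50 tested members of the type I interferon list fell. The MHC class I genes fell with them, B2m from 1384 ± 8.26 to 672 ± 9.68 FPKM (SD, n = 3 each). Cd274, which encodes PD-L1, was also lower. Genes that rose did so by less, among them, after Limch1 itself, the ceruloplasmin gene Cp, the neutrophil chemokine Cxcl5 and the caveolar gene Cavin2.

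Limch1 (ENSMUSG00000037736, mm10 chromosome 5, 66745827 to 67057158, plus strand) was at 24.3 ± 1.23 FPKM in Limch1_OE and at 0.167 ± 0.0764 FPKM in Vector (SD, n = 3 each). Its log2 fold change was 4.44 (SE 0.08, limma adjusted p = 1.89e-09). The values were 23.96, 23.31 and 25.69 FPKM in Limch1_OE replicates 1 to 3 and 0.25, 0.15 and 0.1 FPKM in Vector replicates 1 to 3. The principal protein-coding transcript carried 23.64, 23.03 and 25.63 FPKM in the Limch1_OE libraries and was listed at 0 in each Vector library. The exact permutation test of the group means gave p = 0.1, the smallest that 3 libraries against 3 allow.

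Cd274 (ENSMUSG00000016496, mm10 chromosome 19, 29367455 to 29388095, plus strand, 1 annotated transcript) was at 2.10 ± 0.105 FPKM in Limch1_OE and 7.10 ± 1.05 FPKM in Vector (SD, n = 3 each), a ratio of means of 3.38 in favour of Vector. The log2 fold change was -1.38 (SE 0.10, limma adjusted p = 2.15e-05). The libraries did not overlap, with 2.2, 2.1 and 1.99 FPKM in Limch1_OE and 7.12, 6.04 and 8.13 FPKM in Vector, and the exact permutation p was again 0.1. These values are mRNA levels; PD-L1 protein was not analysed here.

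**Figure D1:**
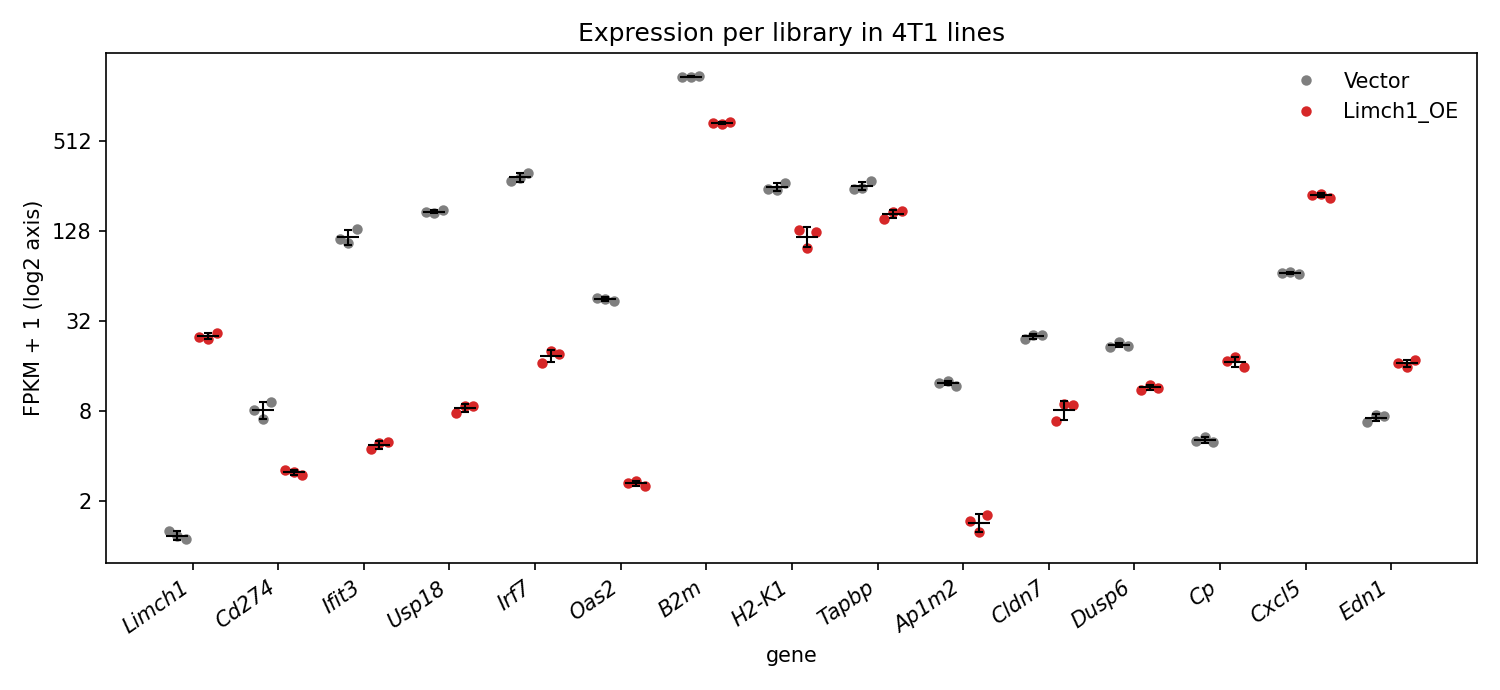
FPKM + 1 on a log2 axis for 15 named genes. Points are the 3 libraries of each group (grey, Vector; red, Limch1_OE), and the black mark and bars are the mean and SD of log2(FPKM + 1). The groups do not overlap for any gene shown, and Usp18 averaged 172 FPKM in Vector and 7.34 FPKM in Limch1_OE.

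Of the type I interferon list, 49 members fell, 1 rose and none of the 50 was left uncalled, with a median log2 fold change of -2.61 (camera adjusted p = 9.05e-58; adjusted p = 0.0568 with an estimated correlation). The lowest fold changes among named genes averaging at least 5 FPKM were -4.71 for Ifit3b and -4.62 for Ifit3, which bind viral RNA or its sensors, -4.57 for the surface antigen gene Ly6a, and -4.37 each for Usp18, an ISG15 protease and brake on interferon receptor signalling, and Cmpk2. They were followed by Rsad2 (viperin, -4.30), the RNase L activator Oas2 (-4.09), Ly6e (-4.00), the transcription factor Irf7 (-3.97), the immunity-related GTPase Iigp1 (-3.89), Ifi44 (-3.86) and Trim30a (-3.60). Oas2 went from 43.6 ± 1.25 FPKM in Vector to 1.61 ± 0.0902 in Limch1_OE (SD, n = 3 each), and Irf7 from 292 ± 18.7 to 17.7 ± 1.75. Oasl2, among the 4 members with the smallest p, fell by 2.76 on the log2 scale. Ifi27 was the exception, at 105 ± 5.90 FPKM in Limch1_OE and 60.7 ± 2.07 in Vector, a log2 fold change of 0.79 (limma adjusted p = 1.15e-05); it was named after its value was seen.

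The following genes of interferon production and signalling were picked after about 22 such genes had been looked up. Ifnb1, encoding interferon beta, was listed at 0 in each Limch1_OE library and at 0.29, 0.29 and 0.34 FPKM in Vector, too low to be tested. The receptor genes Ifnar1 and Ifnar2 rose by 0.35 and 0.76, and Irf3 by 0.34. Tlr3 and Tmem173 (STING) changed by -1.08 and -0.62, and Jak1, Tyk2 and Mavs did not pass the test.

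The interferon-gamma response list had 46 tested members, of which 34 fell, 5 rose and 7 did not pass the test (35 fell and 5 rose adjusted over the list alone). Its median log2 fold change was -1.07 (camera adjusted p = 5.25e-21; adjusted p = 0.0568 with an estimated correlation). The GTPase genes Tgtp1, Tgtp2 and Gbp3 changed by -3.48, -3.35 and -2.69. Gbp3 was at 14.9 ± 0.318 FPKM in Limch1_OE and 102 ± 6.01 in Vector (SD, n = 3 each). Lists share members, so Cd274 and several MHC class I genes count under more than 1 list. Together the interferon and MHC class I lists held 111 tested genes. They supplied 77 of the 214 genes that fell at least 2-fold on the log2(FPKM + 1) scale and 43 of the 76 that fell at least 4-fold.

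Of the MHC class I and antigen processing list, 25 of 27 tested members fell and none rose. The median log2 fold change was -0.71 (camera adjusted p = 2.07e-19; adjusted p = 0.132 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 changed by -2.07 and -0.75, and the immunoproteasome subunit genes Psmb9, Psmb8 and Psmb10 by -1.86, -1.25 and -0.58. Among class I heavy chains the changes were -1.54 for H2-Q6, -1.53 for H2-T22, -1.39 for H2-T23, -1.38 for H2-T10, -1.27 for H2-Q7, -1.18 for H2-Q4, -1.11 for H2-K1, -1.10 for H2-D1, -0.56 for H2-Q10 and -0.36 for H2-M3. B2m, the class I light chain (chromosome 2, 122147686 to 122153083), fell by 1.04 (SE 0.05, limma adjusted p = 6.46e-07). The remaining members that fell were the proteasome activator genes Psme1 (-0.71) and Psme2 (-0.58), the class I transactivator Nlrc5 (-0.68), the peptide-loading genes Tapbp (-0.62), Tapbpl (-0.56) and Calr (-0.48), the trimming peptidase Erap1 (-0.18), and the transcription factors Irf1 (-0.37) and Irf2 (-0.24). With the most abundant transcript of each gene in place of the sum, Tap2 stood at 0.00.

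**Figure D2:**
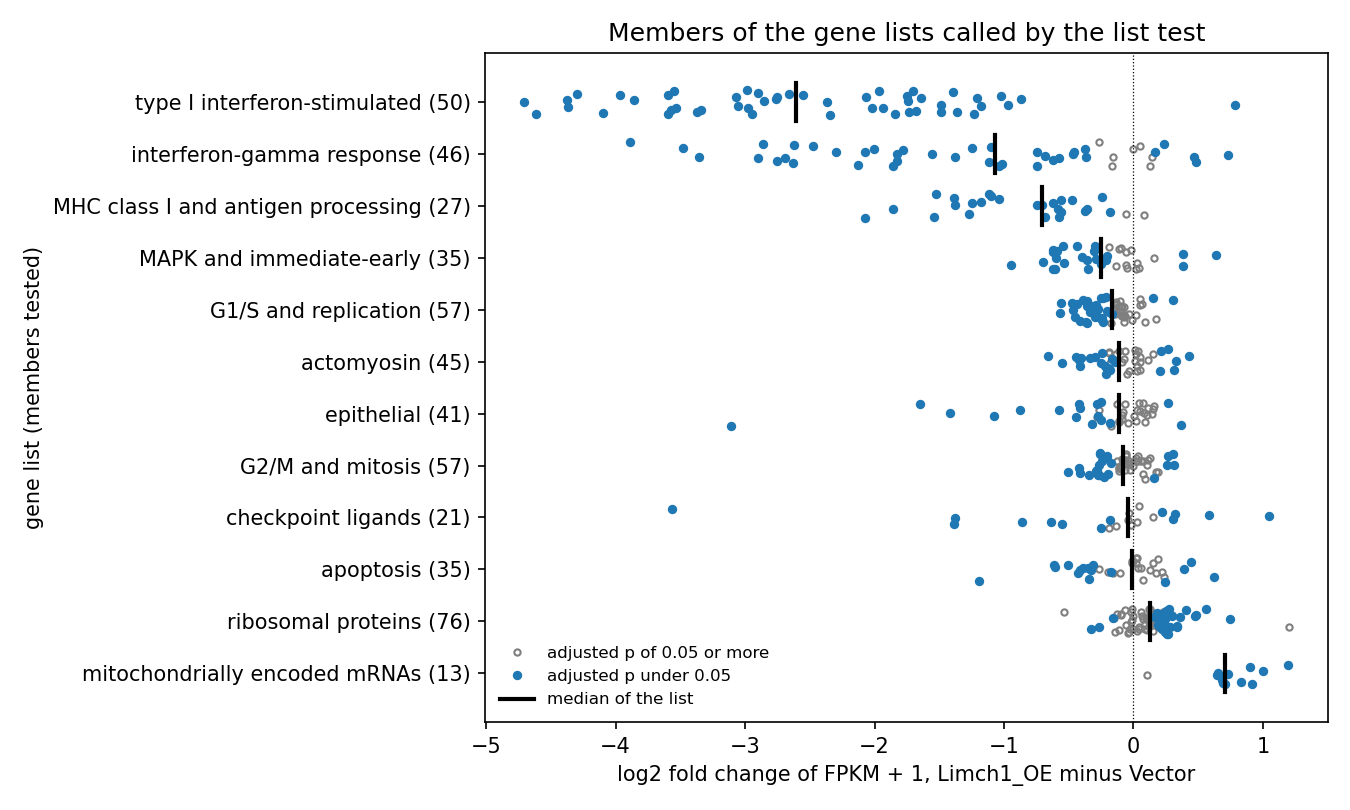
Log2 fold change of FPKM + 1 (Limch1_OE minus Vector) of each tested member of the 12 lists called by camera with the preset correlation. Filled points passed the limma threshold, open points did not, and black lines are list medians, which run from -2.61 for type I interferon genes to 0.71 for mitochondrially encoded mRNAs.

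The checkpoint list, of inhibitory ligands and immunoregulatory factors, had 21 tested members, of which 8 fell and 5 rose (camera adjusted p = 0.0418, lower in Limch1_OE; adjusted p = 0.277 with an estimated correlation and 0.263 without interferon or MHC members). The call ended with the trimmed mean of M values (0.0605), quantile normalization (0.102) and removal of the GC trend (0.0503), and without Limch1_OE replicate 3 (0.0799). Besides H2-T23 and Cd274, those that fell were Lgals9 (galectin-9) from 163 ± 4.63 to 12.9 ± 1.08 FPKM (SD, n = 3 each), Nos2 (-0.86), Havcr2 (-0.63), Tgfb1 (-0.56), Cd276 (-0.25) and Nt5e (-0.18). Those that rose were the NKG2D ligand genes H60b (1.04) and Ulbp1 (0.30), Tgfb2 (0.59), Nectin3 (0.22) and Rae1 (0.32). The symbol Rae1 denotes an mRNA export factor rather than an NKG2D ligand. Of 46 tested regulators of PD-L1, 11 rose and 6 fell (camera adjusted p = 0.941). The ubiquitin ligase gene Trim21 fell by 1.23, the glycosyltransferase gene B3gnt3 changed by -0.63, and the ubiquitin ligase adaptor Spop rose by 0.66. The MHC class II list was mostly low, with 7 of 13 listed genes below 1 FPKM in both groups. Of its 6 tested members, the invariant chain gene Cd74 rose by 0.31 and the protease gene Ctsl changed by -0.22, while Rfxap (-0.24, limma adjusted p = 0.0746) and Rfx5 (-0.09) did not pass (camera adjusted p = 0.665).

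After Limch1, the largest increases among named genes averaging at least 5 FPKM were Cp (log2 fold change 1.74, SE 0.08), Cxcl5 (1.72, SE 0.04), Ddah2 (1.70), Cavin2 (1.56), the cytochrome P450 gene Cyp2c55 (1.47), Lrrn4cl (1.26), the glutathione transferase gene Gsta4 (1.22), the endothelin precursor Edn1 (1.21), mt-Cytb (1.19), the nuclear noncoding RNA Neat1 (1.17) and the carbonyl reductase gene Cbr2 (1.12). Cxcl5 reached 220 ± 6.81 FPKM in Limch1_OE and 66.1 ± 1.02 in Vector (SD, n = 3 each). Of 27 tested chemokines and cytokines, 7 rose and 11 fell, or 8 and 13 adjusted over the list alone (camera adjusted p = 0.0697). By fry this list was called lower (fry adjusted p = 0.0015). Cxcl10, a chemokine for T cells, went from 24.5 ± 0.667 to 3.13 ± 0.295 FPKM, Il1a fell by 1.02 and Lif by 0.68. NF-kB targets were split evenly, with 11 of 41 higher and 11 lower (13 and 14 adjusted over the list alone; camera adjusted p = 0.485), and include Csf3 at -0.75. Of 30 JAK-STAT3 genes 4 rose and 6 fell (camera adjusted p = 0.551), among them Lcn2 (0.74), Junb (-0.54), Mcl1 (-0.35) and Ccnd1 (-0.36).

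Epithelial genes were lower, 15 of 41 against 2 higher (camera adjusted p = 5.51e-04; adjusted p = 0.277 with an estimated correlation). The epithelial sorting adaptor Ap1m2 went from 11.2 ± 0.402 to 0.43 ± 0.191 FPKM (SD, n = 3 each). The claudin genes Cldn7 and Cldn3 changed by -1.65 and -0.88, and the recycling GTPase gene Rab25 by -1.42. Mesenchymal genes went both ways, 9 of 19 higher and 7 lower (camera adjusted p = 0.898). Mmp9 fell by 1.76, whereas Vim rose by 0.63 and Sparc by 0.58. Of 26 matrix genes 11 rose and 9 fell (10 fell adjusted over the list alone; camera adjusted p = 0.782), with the laminin gene Lama3 (-0.74) and Fbln2 (-0.53) lower and Hspg2 (0.71) higher. Of 32 genes of the TGF-beta response 8 rose and 12 fell, including Ccn2 (-0.62), Bhlhe40 (-0.55) and Tgfbr2 (0.58). Camera did not call this list (camera adjusted p = 0.102), whereas fry called it lower (fry adjusted p = 0.0298).

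For the cytoskeleton, 17 of 45 actomyosin genes fell and 6 rose, or 21 and 6 adjusted over the list alone (camera adjusted p = 0.00497; adjusted p = 0.560 with an estimated correlation). The tropomyosin gene Tpm1 (0.43) was among the 6 that rose and the filamin gene Flnc (-0.55) among the 17 that fell. With the most abundant transcript in place of the sum, Tpm1 stood at -0.19. Of 43 focal adhesion genes 10 rose and 11 fell (11 and 13 adjusted over the list alone, camera adjusted p = 0.397). Among them were Ankrd1 (0.46), Fermt1 (-0.49), the integrin gene Itga3 (-0.42) and Csrp1 (-0.43). Of 25 YAP/TAZ targets 5 rose and 6 fell (camera adjusted p = 0.628), with Ankrd1 at 0.46, Birc5 at -0.51 and Tead1 at 0.40. Of 31 LIM-domain and related genes, Limch1 included, 3 rose and 10 fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.182). Zyx (zyxin) changed by -0.46 and Lmo2 by -0.93, the latter from 1.46 to 0.297 FPKM.

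Genes of the G1/S transition and DNA replication were lower by small amounts, 28 of 57 against 2 higher, or 34 and 2 adjusted over the list alone, with a median log2 fold change of -0.17 (camera adjusted p = 9.65e-09; adjusted p = 0.277 with an estimated correlation). The ribonucleotide reductase gene Rrm2 fell by 0.57, the clamp loader gene Rfc3 by 0.47, the polymerase gene Pole2 by 0.48 and Slbp by 0.36. In the G2/M list 17 of 57 fell and 5 rose (18 and 5 adjusted over the list alone; camera adjusted p = 0.00497; adjusted p = 0.488 with an estimated correlation and 0.0585 with quantile normalization), with Birc5 at -0.51, Ccnb2 at -0.34, Ncapd2 at -0.29 and Ckap2l at -0.28. Of 33 listed replication histone genes 31 were below 1 FPKM in both groups. The tested ones were Hist1h1c, which changed by -0.36, and Hist1h2bc (-0.19, limma adjusted p = 0.432). MAPK feedback and immediate-early genes were lower in 20 of 35 cases and higher in 3, with a median of -0.25 (camera adjusted p = 2.93e-06; adjusted p = 0.214 with an estimated correlation). The ERK phosphatase gene Dusp6 fell by 0.94, Etv4 by 0.63 and Epha2 by 0.54, and Fosl2 rose by 0.64.

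In the apoptosis list 12 of 35 members fell and 4 rose (13 and 4 adjusted over the list alone; camera adjusted p = 0.0431; adjusted p = 0.488 with an estimated correlation and 0.0609 without interferon or MHC members). It was 0.0651 with the trimmed mean of M values, 0.0585 with quantile normalization and 0.0543 after removal of the GC trend. It was 0.0850 without Limch1_OE replicate 3, and the call also ended without Limch1_OE replicate 1 or Vector replicate 3. Mlkl and Gsdmd, executioners of necroptosis and pyroptosis, changed by -1.20 and -0.61, Birc5, an inhibitor of apoptosis, by -0.51 and Casp2 by -0.43, so the members that fell include both promoters and inhibitors of cell death. Of 33 p53 targets 8 rose and 6 fell (camera adjusted p = 0.924), with Ddit4 (-0.70) and Plk3 (-0.57) lower and Fas (0.73) and Plk2 (0.34) higher.

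Mitochondrially encoded mRNAs rose in 12 of 13 cases, with a median log2 fold change of 0.71 (camera adjusted p = 4.57e-06; adjusted p = 0.586 with an estimated correlation). mt-Nd3 rose by 0.92 and mt-Co3 by 0.68, mt-Nd2 rose too, and mt-Cytb averaged 2409 ± 580 FPKM in Limch1_OE and 1037 ± 91.5 in Vector (SD, n = 3 each). These mRNAs took 8.2, 5.89 and 6.04% of all FPKM in Limch1_OE replicates 1 to 3 and 5.1, 4.39 and 4.42% in Vector replicates 1 to 3 (exact permutation p = 0.1, the smallest possible). Of 70 nuclear genes of oxidative phosphorylation 8 rose and 7 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.924), with Cox7b (0.38), Ndufs1 (0.39) and Atp5c1 (0.23) higher and Ndufa4 (-0.27) lower. Of 76 cytosolic ribosomal protein genes 26 rose and 3 fell (27 and 3 adjusted over the list alone; camera adjusted p = 0.00496; adjusted p = 0.693 with an estimated correlation and 0.102 with quantile normalization), among them Rpl37a (0.75), Rpl24 (0.49), Rps21 (0.56) and Rps19 (0.29).

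Several RNAs read as signs of RNA quality moved with the groups as well (3 of 6 higher, 2 lower). Camera did not call their list (camera adjusted p = 0.532), whereas fry called it higher (fry adjusted p = 0.00594). The nuclear-retained Malat1 was at 83.2 ± 7.29 FPKM in Limch1_OE and 42.3 ± 2.59 in Vector (SD, n = 3 each), Neat1 at 49.1 ± 10.3 and 21.1 ± 2.59, and Gas5 rose by 0.43, while Rn7sk changed by -0.91. Retained-intron transcripts held 3.48 ± 0.23% of FPKM in Limch1_OE and 3.37 ± 0.101% in Vector (exact permutation p = 0.5). Among 18 reference genes B2m fell and Pgk1 (0.22), Tfrc (0.21) and Gusb (0.16) rose, or 1 each way adjusted over the list alone (camera adjusted p = 0.628). With the trimmed mean of M values, 1 reference gene was higher and 3 were lower.

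**Figure D3:**
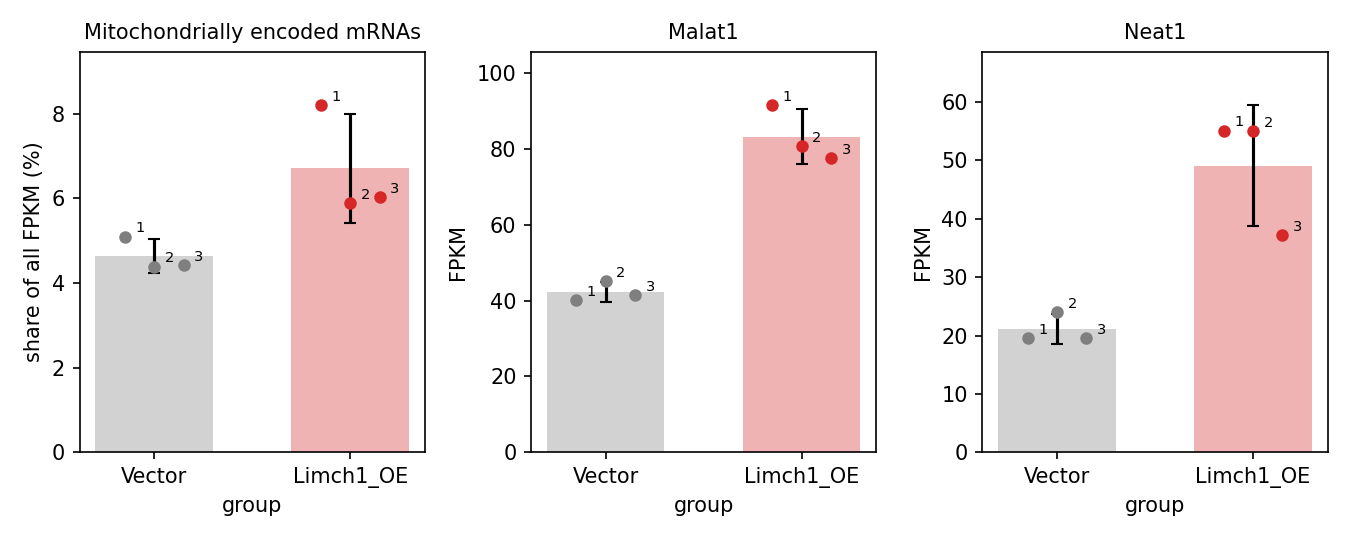
Share of all FPKM held by mitochondrially encoded mRNAs (left, percent) and FPKM of Malat1 and Neat1 (middle and right) in each group. Bars are means with SD of 3 libraries and numbered points are replicates; Limch1_OE replicate 1 has the highest mitochondrial share, 8.2%.

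Markers of other cell types were near zero for the most part. Of 15 listed leukocyte markers 12 were below 1 FPKM in both groups, and the others, which tumour cells also express, were Cd68 (0.31), Lcp1 (-0.45) and Cd14 (-0.28). Below 1 FPKM in both groups were also 7 of 10 fibroblast markers, 9 of 12 endothelial markers and 7 of 8 adipocyte and muscle markers. The fibroblast markers above that level were S100a4 (0.42), Postn (0.41) and Pdgfra (0.23, limma adjusted p = 0.0881), of which 3 rose adjusted over the list alone and 2 over all genes. The endothelial ones were Eng (-0.37), Flt1 (0.38) and Egfl7 (-0.14, limma adjusted p = 0.340). Mb (myoglobin), the remaining muscle marker, was at 0.427 ± 0.119 FPKM in Limch1_OE and 3.57 ± 0.518 in Vector.

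The metabolic, stress and other signalling lists were not called by camera. Of those that follow, fry called the fatty acid list higher (fry adjusted p = 0.0206) and the Wnt list lower (fry adjusted p = 0.0326). Of 27 genes of fatty acid metabolism 8 rose and 3 fell (camera adjusted p = 0.862), led by the desaturase gene Scd2 (0.83), Plin2 of lipid droplets (-0.86), Cpt1a (-0.42) and Fads1 (0.29). Cholesterol synthesis had 4 higher and 3 lower of 24 (camera adjusted p = 0.847; Cyp51 -0.47, Mvd 0.41, Ebp 0.22). Glycolysis had 7 higher and 3 lower of 26, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.898; Pdha1 0.39, Aldoc 0.66, Slc16a1 -0.24, Pdhb -0.31). The NRF2 list had 4 higher and 5 lower of 29 (camera adjusted p = 0.551), with Gsta4 at 1.22, the ferritin gene Fth1 at -0.48, Hmox1 at -0.47 and Me1 at -0.26. Of 33 hypoxia genes 8 rose and 6 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.941). Vegfa (0.56) and Ndrg1 (0.34) were among those that rose, and Ddit4 (-0.70) and Bhlhe40 (-0.55) among those that fell. The unfolded protein response and ATF4 list had 10 higher and 14 lower of 47 (11 and 14 adjusted over the list alone; camera adjusted p = 0.416; Atf5 0.61, Psph -0.52).

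Among lysosome and autophagy genes 10 of 45 rose and 9 fell (11 and 9 adjusted over the list alone; camera adjusted p = 0.924). The sterol carrier gene Npc2 changed by -1.04, Hexa by -0.94, Ctsz by 0.48 and Atp6ap1 by 0.31, which was -0.54 with the most abundant transcript in place of the sum. Of 56 deubiquitinating enzymes 11 rose and 9 fell (12 and 9 adjusted over the list alone; camera adjusted p = 0.898), with Usp25 (-0.54), Otub2 (-0.48) and Usp9x (0.67) next to Usp18. Of 21 Wnt genes 1 rose and 5 fell (camera adjusted p = 0.113); Ctnnb1, encoding beta-catenin, rose by 0.53, and Wnt7a and Wnt7b fell by 0.38 and 0.26. Of 17 Notch genes 2 rose and 3 fell (camera adjusted p = 0.592; Psen2 0.40, Numb -0.31, Hes6 0.32). The list test pointed down although the median was above 0 for PD-L1 regulators, NF-kB targets, unfolded protein response, hypoxia, cholesterol, lysosome and deubiquitinating enzymes, and although the mean was above 0 for matrix, hypoxia, cholesterol and LIM-domain genes. Its direction changed with the scaling for PD-L1 regulators, p53 targets, hypoxia, oxidative phosphorylation, lysosome and deubiquitinating enzymes. For the lists given no second count, the calls adjusted over the list alone were as many as those over all genes.

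Some named genes moved by over 1.5 times or lost their call under another choice. With the most abundant transcript in place of the sum, Cp stood at 0.88, Tap1 at -1.20, Psmb8 at -2.51, where its call ended, Psen2 at 2.28, Itga3 at -0.72 and Rfx5 at -1.78, still uncalled. There Irf2 (-0.06), Zyx (-0.20), Ndufs1 (0.16) and Atp5c1 (0.115) lost their calls, as did Ly6a (-3.38, limma adjusted p = 0.0786), Psme2, Flnc, Fbln2, Eng, Otub2 and Wnt7b, and Egfl7, uncalled, was at -0.49. With a pseudocount of 0.1, which weighs low values more, Lmo2 was at -2.02, Mb at -2.82, Tgfb2 at 1.13, Havcr2 at -0.99, H2-Q10 at -0.86 and Pdgfra at 0.35. After removal of the GC trend Erap1 was at -0.30 and Ulbp1 at 0.18, while Nectin3 was at 0.13 and Tfrc at 0.05. Leaving out 1 library moved the uncalled Egfl7 to -0.07 (without Limch1_OE replicate 1), to -0.09 (without replicate 3) and to -0.26 (without replicate 2), and the uncalled Rfx5 to -0.05 (without Limch1_OE replicate 1). Calls close to the threshold ended under several alternatives: Nectin3 in 14 of 21, Irf2 in 11 of 22, Tfrc in 10, Erap1 and Gusb in 9 each, Cd14 in 7, Cd68 and Nt5e in 6 each, Numb and Hes6 in 5 each and Psme2 in 3.

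In all, 2388 of 11842 tested genes (20.2%) were higher in Limch1_OE and 1706 (14.4%) lower at a limma adjusted p under 0.05. At least 2-fold on the log2(FPKM + 1) scale, 36 were higher and 214 lower, and at least 4-fold, 1 was higher (Limch1) and 76 were lower. Groups did not overlap for 5809 genes (49.1%), where chance gives 10%. The split of small changes moved with the scaling: 1911 genes were higher and 2048 lower with the trimmed mean of M values, and 2003 higher and 2379 lower after removal of each library's GC trend. Of the 37 lists tested, 10 were called lower and 2 higher with the preset correlation, none was called with an estimated correlation, and fry called 17.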

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

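The alternatives named as added in the methods were chosen after seeing the data. Limch1 and Cd274 kept their direction and their side of the threshold in all 22 alternatives that test single genes, Limch1 between 4.40 and 6.55 (highest adjusted p = 4.47e-06) and Cd274 between -1.70 and -1.29 (highest adjusted p = 0.00121). Camera with an estimated correlation called 0 lists, against 8 (quantile normalization) to 17 (fry) in the other list alternatives. A minimum fold of 1.2 left 239 genes higher and 414 lower, since it asks for larger changes. The most abundant transcript per gene gave 997 higher and 999 lower, and with it Tpm1 (-0.19), Hes6 (-0.0908), Atp6ap1 (-0.54), Postn (-0.34) and Tap2 (0.0027) reversed; the cause was not tested. Leaving out 1 library at a time gave 1597 to 2225 genes higher, 1285 to 1553 lower and 10 to 12 lists, Limch1 at 4.40 to 4.49, Cd274 at -1.48 to -1.29 and Hist1h2bc, never called, at -0.314 to 0.0156, above 0 without Limch1_OE replicate 1. The tested genes stayed those of all 6 libraries. The counts of genes higher and lower were lowest without Vector replicate 1, and the count of lists without Limch1_OE replicate 3. Of 4095 alternative values for 188 named genes 3931 kept direction and call, 155 lost the call, 3 gained it and 6 reversed. The checkpoint and apoptosis lists each lost their call in 9 of 24 alternatives, G2/M in 3 and the ribosomal list in 2. Equal replicate numbers did not pair the libraries (correlations -0.0017, 0.046 and 0.059); a replicate block gave 2219 higher and 1589 lower and ended the checkpoint call. Tests on counts were not run, since no counts are listed, and depth limits cannot be given.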

Other observations

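Chosen after the result was seen were the tests on leukocyte markers, Cd274 with its list, Limch1_OE replicate 1 and low GC content. So were those on mitochondrial rRNA, random placement and zinc finger genes. The others were set before it, but some of their settings were added after seeing the data. These are removal of the GC trend (scaling test and GC content of the region) and removal of mitochondrial genes (scaling test).

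The lower interferon-stimulated genes do not come from scaling alone, since the median of the type I interferon list closest to 0 over 6 scalings was -2.55. GC content and transcript length leave it as well: members differed from genes matched on both by a median of -2.61. Leukocytes mixed into Vector would bring their own transcripts, but the highest Vector mean among 7 leukocyte markers was 0.243 FPKM (Csf1r). These 7 were picked without the 3 markers expressed in both groups, of which Lcp1 (-0.45) and Cd14 (-0.28) fell and Cd68 (0.31) rose. Of all 15 listed markers 12 were below 1 FPKM in both groups. Cd274 lay at percentile 42.2 of the other 45 tested interferon-gamma list members, so its decrease is in line with the list by this test, which does not show a shared cause. Whether Limch1, the separate selection of the lines or their state at infection lowered these genes stays open. The groups differ in Limch1 and in the selected line together, and the labels do not give the state at infection. No uninfected library was analysed here.

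The higher mitochondrial mRNAs do not rest on Limch1_OE replicate 1, since without it the median of the 13 mRNAs was 0.612. Low GC content accounts for part at most: nuclear genes of nearest GC content had a median of 0.279, and the mitochondrial mRNAs exceeded them by 0.495. More mitochondrial RNA of every kind would raise both rRNAs, but mt-Rnr1 fell (log2 fold change -1.01) and mt-Rnr2 did not pass the test (0.31, limma adjusted p = 0.287). How rRNA removal or poly(A) selection differed between libraries is unknown, so these rRNAs cannot decide whether all mitochondrial RNA rose. A technical cause in RNA handling stays open beside a biological one.

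Neighbouring genes shifted together: of 975 windows of 40 coding genes, that from Shroom4 to Fundc1 on chromosome X (6399854 to 17572325) had a median of 0.345 against 0.0353 genome-wide, with 28 genes higher and 1 lower. None of 1000 random placements had a window as far out (permutation p = 0.001, the smallest they can give). GC content of the region left a distance of 0.288, and the window held 0 genes of the interferon or MHC lists and 0 zinc finger genes, so neither group accounts for it. Windows overlapped along each chromosome, so counts of windows are not counts of separate regions. Of 28 windows beyond the 95th percentile of the placements 9 held no zinc finger gene. Without these genes 19 of the 28 stayed beyond it, or 21 against the median of all genes. The part of zinc finger genes in the other windows is thus undecided. The shifts went both ways and reached over whole chromosomes. On chromosome X 130 of 299 coding genes were higher and 17 lower, and on chromosome 6 23 of 479 were higher and 153 lower. After removal of the GC trend the medians of these chromosomes were 0.109 and -0.148. A copy-number difference between the selected lines may be a candidate explanation, which was not tested because no DNA data were used here.

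With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2388 genes higher, 1706 lower and 12 lists, matched by 1 split each, the real one, and the highest of the other splits gave 1, 1 and 11. Each of the other splits mixes libraries of both groups, so the difference between groups counts there as spread. Their low gene counts were thereby fixed in advance and cannot serve as a null. Their list counts ran from 5 to 11, close to the real 12 at the upper end. These splits hold unequal numbers of each group, so part of the group difference remains in them. The list counts therefore cannot serve as a null either, and do not show how many lists are called by chance.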
